A study of Mus musculus with 16 samples.

How the data were processed

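RNA sequencing was carried out on 16 libraries of mouse embryo head tissue taken at embryonic day 8.5. The labels place 4 libraries in each of 4 groups: wild type embryos and embryos without a functional Ift88 gene, on a moderate diet (2 ppm folic acid) or an enriched diet (10 ppm), kept for 3 generations. Per the labels' protocols, RNA was extracted with an AllPrep kit and libraries were made with a TruSeq RNA kit, version 2, which keeps no strand information. Reads on overlapping or antisense genes therefore cannot be assigned with certainty, nor can those on near-identical paralogs, which share sequence. The labels name the embryos by replicate number, genotype, diet and sex, and give no litter. Whether the 4 embryos of a group came from separate litters is not given in the sources used here, so p-values measure the spread between these libraries.

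Per the submitters' processing notes, the authors checked reads with FastQC 0.11.5, aligned them to the mouse genome build mm10 with TopHat2 2.1.1, sorted alignments with SAMtools 1.8, counted reads per gene with HTSeq 0.9.1 and tested genes with DESeq2 1.22.2. The notes give neither the counting mode, the strand option nor the annotation that was used. The deposited values are raw read counts per gene symbol, without normalization, for 24421 genes in each library, followed by 5 summary lines of the counting tool. Those lines were left out of all totals and tests. Reads on no annotated feature came to 13.7 to 17.0% of the uniquely aligned total, ambiguous reads to 1.20 to 1.39%, and alignments of reads with several positions to between 77.2 and 94.9 per 100 assigned reads. Totals assigned to genes ranged from 19249433 to 44267434 counts per library. Coordinates were taken from the GENCODE vM21 annotation of the same build by symbol, which matched 23376 of the 24421 symbols and 14010 of the genes tested. The annotation behind the deposited counts may differ from it.

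The counts were tested with edgeR 4.0.16 and limma 3.58.1 in R 4.3.3. Genes were kept with at least 10 counts in at least 4 libraries, which left 14514 genes, or 59.4% of those listed. Counts were scaled with trimmed means of M values, and a quasi-likelihood model was fitted to all 16 libraries with a coefficient for each group and the sex given by the labels as a covariate. The contrasts were genotype on each diet, diet in each genotype, the difference between the 2 genotype effects, and the averages over diet and over genotype. Adjusted p-values are Benjamini-Hochberg values over the genes tested in a contrast, with a threshold of 0.05. The standard error of a log2 fold change is its size divided by the square root of the F statistic. CPM values are counts-per-million of the scaled library total. A principal component analysis used the 500 genes with the largest variance of log2 CPM.

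Gene lists were written from general knowledge. Of these, 35 had at least 5 tested genes and were tested with camera at a preset correlation of 0.01 on log2 CPM with voom weights, against all other genes tested. The same lists were tested with a correlation estimated from the data and with fry, which asks whether the genes of a list move on balance in one direction. Adjusted p-values of the lists are Benjamini-Hochberg values over the lists of a contrast. Members of a list are counted as past the threshold over all genes and, separately, adjusted over the list alone. The score of a list in a library is the mean over its genes of log2 CPM, computed with a prior count of 2 and centred on the mean of the 16 libraries. Some genes sit on several lists, and many markers of other cell types are also made by embryonic head tissue.

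Genes named in a contrast are Ift88, then up to 10 with the largest rise and 10 with the largest fall among those past the threshold with a mean CPM of at least 1. Genes whose libraries do not overlap between the groups came first. Sex-linked genes and symbols of predicted genes were passed over. Of each list, the 4 genes with the smallest p are named, and where fewer than 5 genes of a contrast passed, the 5 with the smallest p. These rules, the tests, the lists and most alternatives were fixed before the data were examined. Names outside the rules are given as such, and some genes within them are not reported here.

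The alternatives were median-of-ratios scaling, the Wald test of DESeq2 1.42.0, limma-voom, no filter on low counts, a filter on a CPM of at least 1 in 4 libraries, no sex covariate, sex read from Xist and Y-linked counts, the replicate number as a block, the libraries of the groups compared alone, an adjusted p of 0.1, no sex-linked genes, and leaving out each library in turn. Leaving out the 3 libraries whose sex label differs from their counts, or 3 libraries with unusual values, was added after the data were seen. Every other split of the libraries into groups of the same size was counted for contrasts of 2 groups, and 100 splits were drawn for the others. The model was tested on simulated data, in which 50 genes at each of 4 fold changes were shifted among the 14514 and the share recovered was recorded. The spread of each simulated gene was estimated over all 16 libraries together, alike for every contrast. Each of the 24 pairs of libraries within a group was checked for duplication. Their chi-square per gene ran from 6.49 to 66.6, so no pair was the same library counted again.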

Results

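Gene expression was measured by RNA sequencing in the heads of mouse embryos at embryonic day 8.5, from the first branchial arch up to a level just above the otic vesicle. The embryos either carried a functional Ift88 gene or lacked it. Ift88 encodes a subunit of the particle that moves cargo along cilia, and cells without it fail to build cilia and to respond normally to Hedgehog signals. Their families had been kept for 3 generations on a diet with 2 ppm folic acid, called moderate, or 10 ppm, called enriched. The series concerns the effect of folic acid supplementation on cilia, so the design asks what the loss of Ift88 and the diet each change, and whether one alters the effect of the other. Each of the 4 groups held 4 libraries. Totals assigned to genes ran from 20875382 to 39744994 counts in moderate diet wild type, 25080849 to 36442710 in moderate diet mutants, 20760316 to 33858563 in enriched diet wild type and 19249433 to 44267434 in enriched diet mutants. The first principal component held 47.6% of the variance and separated the genotypes. Its mean position was -17.9 ± 1.93 (SD, n = 4) in moderate diet wild type, -15.7 ± 2.37 in enriched diet wild type, 12.5 ± 11.1 in moderate diet mutants and 21.0 ± 2.88 in enriched diet mutants. Moderate diet mutant replicate 3 lay at -3.66, apart from the other moderate diet mutants at 14.7 to 21.2. In 3 libraries, moderate diet wild type replicate 2 and moderate diet mutant replicates 1 and 2, Xist and Y-linked counts contradicted the sex on the label.

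Ift88, on chromosome 14 from 57424062 to 57517936 of mm10, served as the check of the labels. Its level in moderate diet wild type replicates 1 to 4 was 19.9, 9.30, 20.9 and 20.7 CPM, a mean of 17.7 ± 5.63 (SD, n = 4). Enriched diet wild type replicates 1 to 4 held 18.98, 20.7, 17.9 and 20.8 CPM (19.6 ± 1.42). Moderate diet mutants held 3.35, 6.44, 2.01 and 3.44 CPM (3.81 ± 1.87), and enriched diet mutants 2.99, 8.61, 2.86 and 5.25 CPM (4.93 ± 2.69). All 8 mutants lay below all 8 wild type libraries, but the library labelled moderate diet wild type replicate 2 reached only 46.5% of the mean of the other 7 wild type libraries, 19.98 ± 1.17 CPM. Mutants kept 10.0 to 43.1% of that mean, so reads from the locus were still counted. Which exons the allele lacks is not given in the sources used here. The log2 fold change in mutants was -2.22 ± 0.35 (SE) on the moderate diet (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.000927) and -1.97 ± 0.34 on the enriched diet (adjusted p = 0.000822).

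**Figure D1:**
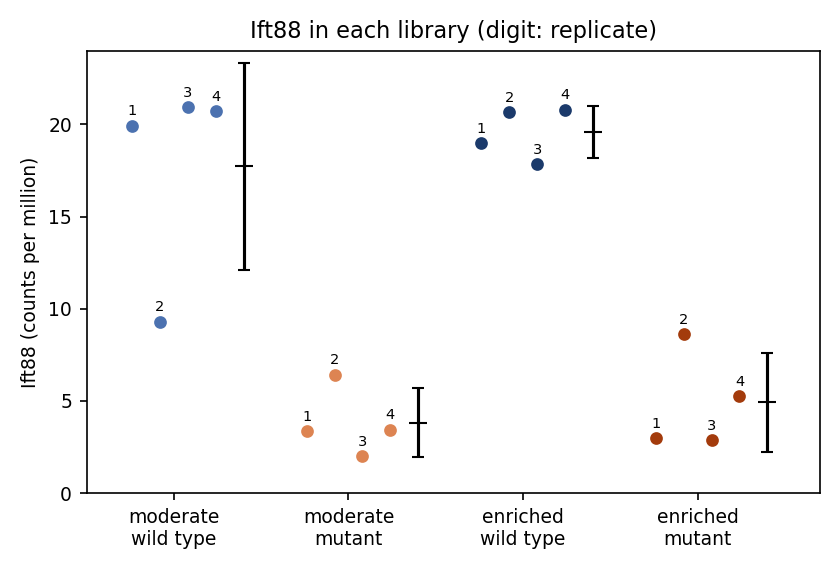
Ift88 in counts-per-million (CPM) in each of the 16 libraries, by group; points are libraries and bars show the mean and SD of 4. The mutants lie between 2.01 and 8.61 CPM, and one wild type library on the moderate diet lies at 9.30 CPM, below the other 7 at 17.9 to 20.9 CPM.

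On the moderate diet, mutants lost genes of the ventral midline of the neural tube. Shh, the Hedgehog ligand made by the floor plate, fell from 34.1 ± 0.875 to 1.55 ± 0.537 CPM (SD, n = 4). Foxa2, the transcription factor of the floor plate, fell from 15.4 to 0.445 CPM, and Nkx2-9, which Hedgehog signals switch on beside the floor plate, from 16.9 to 0.0722 CPM. Genes of the response to low oxygen were higher, a list call lost with an estimated correlation (adjusted p = 0.0738). Adm, the vasodilator peptide adrenomedullin, went from 0.604 ± 0.183 to 26.1 ± 14.2 CPM, with replicate 3 at 4.84 CPM and the other mutants at 32.0 to 34.4 CPM, and Ddit4, an inhibitor of growth signalling, from 43.3 to 401.0 CPM. In all, 1106 of 14514 genes passed the threshold, of which 695 rose and 411 fell, and 284 changed by more than 2-fold (175 up, 109 down).

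The largest falls by the naming rule were in Nkx2-9 (log2 fold change -7.81 ± 0.30 SE, edgeR Benjamini-Hochberg adjusted p = 8.55e-11), Foxa2 (-5.09 ± 0.19, adjusted p = 8.55e-11) and Shh (-4.43 ± 0.19, adjusted p = 2.69e-10). Shh lies on chromosome 5 from 28456815 to 28467256, Foxa2 on chromosome 2 from 148042877 to 148046969 and Nkx2-9 on chromosome 12 from 56611389 to 56613284. The mesenchymal factors Foxl1 (-3.60) and Foxf2 (-2.50), Ferd3l of the floor plate (-3.34), Nkx2-2 of ventral progenitors (-3.03), the retinaldehyde dehydrogenase Aldh1a1 (-2.70) and the Wnt antagonist Dkk2 (-2.34, with mutant replicate 3 at 3.15 CPM and the other mutants at 0.287 to 0.581 CPM) followed. The largest rises by that rule, which puts genes whose libraries do not overlap first, were in Adm (5.37 ± 0.53, adjusted p = 1.61e-05), which lies on chromosome 7 from 110627661 to 110629820, and in Bhlhe40 (4.35), Ier3 (3.86), Ndufa4l2 (3.83), Bhlhe41 (3.47), Gata4 (3.30), Ddit4 (3.20), Ppp1r3c (3.12), Stc2 (2.96) and Stc1 (2.95). Most of these, such as the repressors Bhlhe40 and Bhlhe41 and the mitochondrial subunit Ndufa4l2, are known to be induced in low oxygen. Gata4 is a factor of heart and endoderm, and its mean in mutants was 1.85 CPM. In each of these genes all 4 mutants lay on the same side of all 4 wild type libraries.

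Floor plate and ventral neural tube genes fell as a list (camera Benjamini-Hochberg adjusted p = 5.90e-15; adjusted p = 0.00104 with an estimated correlation), with 1 gene up, 11 down and 7 not past the threshold, and 1 up and 15 down adjusted over the list alone. Hedgehog-induced genes, of which 6 are also on the floor plate list, fell as a list (adjusted p = 8.60e-08, and adjusted p = 0.0738 with an estimated correlation). Their log2 fold changes had a median of -0.55 and a mean of -1.27. Of these Hedgehog-induced genes 3 rose, 10 fell and 9 did not pass, and 4 rose and 12 fell adjusted over the list alone. Hsd11b2, a steroid dehydrogenase, was among them (-1.63 ± 0.14). Gli1, the readout of the pathway, fell by 1.54 ± 0.24 on the log2 scale, and the receptor Ptch1 fell by 0.50, genes chosen after their values were seen. The call of Ptch1 was lost in 8 of 19 alternatives and that of Gli1 in 1, without the 3 libraries with a contradicted sex label. The components of the Hedgehog pathway did not pass against the other genes (adjusted p = 0.202) but did by fry (adjusted p = 0.0259), with 1 up, 1 down and 23 not past the threshold, and Fuz, an effector of planar polarity, up by 0.57. Forebrain and midbrain genes went both ways (adjusted p = 0.241), with 1 up, 5 down and 14 not past the threshold, or 3 up and 5 down adjusted over the list alone. Wnt8b (-1.14), Emx2 (-1.21) and Nkx2-1 (-1.84) were among the falls. Of the head mesoderm and pharyngeal endoderm genes (adjusted p = 0.0968) none rose, 5 fell and 11 did not pass, or 2 up and 5 down adjusted over the list alone, with Foxc2 at -0.85 and Fgf10 at -0.86.

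Hypoxia and glycolysis genes rose with 22 of 24 past the threshold and none down, also when adjusted over the list alone (camera Benjamini-Hochberg adjusted p = 5.47e-28; adjusted p = 0.0738 with an estimated correlation). The glycolytic enzymes Pfkl (0.84 ± 0.08), Tpi1 (1.08 ± 0.11) and Pfkp (2.34 ± 0.25) were among the surest. Of the response to amino acid shortage and endoplasmic reticulum stress, 13 of 24 genes rose and none fell, or 14 adjusted over the list alone (adjusted p = 1.00e-06; adjusted p = 0.474 with an estimated correlation), with the glutathione-degrading Chac1 at 4.64 ± 0.75, Vldlr at 2.56 ± 0.37 and the asparagine synthetase Asns at 1.08 ± 0.19. The call of Chac1 was lost with limma-voom (adjusted p = 0.172) and without the 3 libraries with a contradicted sex label (edgeR adjusted p = 0.0941). Immediate early genes rose (adjusted p = 0.000106; adjusted p = 0.426 with an estimated correlation), 5 of 18 over all genes and 7 adjusted over the list alone, with Atf3 at 1.69 and Ier3 at 3.86. Moderate diet mutant replicate 3 shared the rise of hypoxia genes only in part, with a score of -0.164 where the other 7 mutants held 0.658 to 0.965 and wild type -0.859 to -0.394. Its amino acid and endoplasmic reticulum stress score of -0.507 lay inside the wild type range. Without that library, 2107 genes passed, of which 1068 were shared with the 1106.

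Markers of other cell types moved beside these groups. Erythroid genes fell (camera Benjamini-Hochberg adjusted p = 4.87e-05; adjusted p = 0.488 with an estimated correlation) by a median of 0.97 on the log2 scale, and 1 of 15, the erythropoietin receptor Epor, passed, or 10 adjusted over the list alone. Endothelial genes rose, 5 of 19 both over all genes and adjusted over the list alone, with the receptor Flt1 up by 0.83, but the call (adjusted p = 0.0434; adjusted p = 0.488 with an estimated correlation) was lost without moderate diet mutant replicate 1 or 3 or moderate diet wild type replicate 1 or 2, at 0.0764 to 0.132. Cardiomyocyte genes (adjusted p = 0.316) and yolk sac and visceral endoderm genes (adjusted p = 0.319) did not pass as lists. Surface ectoderm and placode genes rose (adjusted p = 0.00166; adjusted p = 0.428 with an estimated correlation), 4 of 20 and 6 adjusted over the list alone, with the keratin Krt19 at 1.06. Targets of BMP and TGF-beta rose (adjusted p = 0.00466; adjusted p = 0.474 with an estimated correlation), with 5 up and 1 down of 19, or 7 up and 1 down adjusted over the list alone, and with Id4 at -1.20. Early neuron genes fell as a list (adjusted p = 0.00865; adjusted p = 0.555 with an estimated correlation) without a single gene past the threshold, or 2 adjusted over the list alone, and this call was lost without moderate diet mutant replicate 3 (0.162) or moderate diet wild type replicate 4 (0.242).

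Of 28 subunits of intraflagellar transport and ciliary motors, 4 rose and 1 fell, the same numbers adjusted over the list alone, and the fall was Ift88 itself (camera Benjamini-Hochberg adjusted p = 0.140 for the list). Hspb11 rose by 0.69, Ift52 by 0.33 and Dync2li1 by 0.35. Of the transition zone and BBSome, 2 of 28 rose, or 3 adjusted over the list alone (adjusted p = 0.538), and motile cilia genes did not pass (adjusted p = 0.152). Folate transport and one-carbon genes went both ways (adjusted p = 0.362), 6 up and 1 down of 36, or 6 up and 2 down adjusted over the list alone. The mitochondrial enzymes Shmt2 (0.86 ± 0.11), Mthfd1l (0.65) and Mthfd2 (0.81) rose, and the folate receptor Folr1 fell by 1.218 ± 0.26. The DNA methylation machinery (adjusted p = 0.671), imprinted genes (adjusted p = 0.362) and p53 targets (adjusted p = 0.0840) did not pass as lists. Cholesterol synthesis genes fell (adjusted p = 0.000234; adjusted p = 0.488 with an estimated correlation), with 1 of 24 past the threshold and 5 adjusted over the list alone. On simulated data with the spread estimated over all 16 libraries the test recovered 16% of genes changed 1.25-fold, 54% at 1.5-fold, 82% at 2-fold and 94% at 4-fold. Any larger spread among moderate diet mutants was averaged with that of the other groups, so recovery in this comparison may be lower. The count of 1106 changed with the libraries used. It was 2107 without moderate diet mutant replicate 3, 538 to 784 without any 1 of the other 7 libraries, and 105 without the 3 libraries with a contradicted sex label. That last fit kept only replicates 3 and 4 of the moderate diet mutants. With the sex read from counts and every library kept, 1080 genes passed, of which 992 were shared with the 1106.

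On the enriched diet the loss of Ift88 removed the same ventral genes. Shh fell from 33.9 ± 2.64 to 1.10 ± 0.277 CPM (SD, n = 4), Foxa2 from 16.8 to 0.432 CPM and Nkx2-9 from 17.9 to 0.0520 CPM. Adm rose from 0.946 ± 0.210 to 37.4 ± 9.84 CPM, and Chac1, an enzyme of the stress response, from 1.24 to 41.8 CPM. The mean score of cholesterol synthesis genes went from 0.237 ± 0.145 to -0.315 ± 0.148 in log2 units, a list call lost with an estimated correlation (adjusted p = 0.582). The threshold was passed by 4524 of 14514 genes, 2091 up and 2433 down, of which 600 changed by more than 2-fold (401 up, 199 down).

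Among the largest falls were Nkx2-9 (-8.30 ± 0.32 SE, edgeR Benjamini-Hochberg adjusted p = 7.65e-11), Foxa2 (-5.19 ± 0.20, adjusted p = 7.65e-11) and Shh (-4.89 ± 0.20, adjusted p = 1.36e-10). Nkx2-2 (-4.03), Foxl1 (-3.84), Dkk2 (-3.52), Ferd3l (-3.35), Aldh1a1 (-3.17) and Foxf2 (-2.72) followed. Adm (5.37 ± 0.50, adjusted p = 1.25e-05), Chac1 (5.18 ± 0.76, adjusted p = 0.000303), Bhlhe40 (4.91), the chromatin reader Trim66 (4.87), Ier3 (4.46), the glycolytic enzyme Eno2 (4.13), the pseudokinase Trib3 (4.10), Bhlhe41 (3.72) and Nxph4 (3.64) rose most with all 4 mutants above all 4 wild type libraries. The rule also named Prl8a2, a prolactin-like hormone of the maternal decidua (7.04 ± 2.08, adjusted p = 0.0183). Its level rested on enriched diet mutant replicate 3, at 189 CPM against at most 3.46 CPM elsewhere. Without that library it had too few counts to be tested, and with limma-voom its adjusted p was 0.355, in a range of 0.00141 to 0.355 over 12 alternatives.

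Floor plate genes fell (camera Benjamini-Hochberg adjusted p = 1.95e-09; adjusted p = 0.00962 with an estimated correlation), none up, 13 down and 6 not past the threshold, or 1 up and 13 down adjusted over the list alone. Hedgehog-induced genes fell (adjusted p = 2.29e-05; adjusted p = 0.316 with an estimated correlation) with 2 up, 13 down and 7 not past, or 3 up and 13 down adjusted over the list alone, and Hsd11b2 at -1.92. Gli1 fell by 1.25 and Ptch1 by 0.37, again chosen after their values were seen, and the call of Ptch1 was lost in 12 of 19 alternatives. Hypoxia and glycolysis genes rose (adjusted p = 2.69e-15; adjusted p = 0.353 with an estimated correlation), 22 of 24 and none down, also adjusted over the list alone, with the prolyl hydroxylase P4ha1 at 1.27 and the demethylase Kdm3a at 1.12. Amino acid and endoplasmic reticulum stress genes rose (adjusted p = 6.11e-07; adjusted p = 0.582 with an estimated correlation), 17 up and 2 down of 24, or 18 up and 3 down adjusted over the list alone, with Asns at 1.65, Vldlr at 2.96, Pck2 at 2.23 and Ddit3 at 1.92. Immediate early genes rose (adjusted p = 0.00255; adjusted p = 0.582 with an estimated correlation), 9 up and 1 down of 18, or 10 up and 1 down adjusted over the list alone, with Nr4a1 at 0.71.

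Cholesterol synthesis genes fell on this diet (camera Benjamini-Hochberg adjusted p = 1.48e-09; adjusted p = 0.582 with an estimated correlation), none up, 19 down and 5 not past of 24, or 22 down adjusted over the list alone. Mvd fell by 0.70 on the log2 scale, Nsdhl by 0.85 and Fdps by 0.87. S phase and replication genes fell (adjusted p = 6.20e-05; adjusted p = 0.755 with an estimated correlation), 1 up and 13 down of 24, or 1 up and 14 down adjusted over the list alone, with the nuclease Fen1 at -0.63 and the thymidylate synthase Tyms at -0.64. Erythroid genes fell here too (adjusted p = 0.0163; adjusted p = 0.772 with an estimated correlation), 5 of 15 or 6 adjusted over the list alone, with Klf1 at -1.79, a call lost without enriched diet mutant replicate 4 (0.264). BMP and TGF-beta targets rose (adjusted p = 0.0163; adjusted p = 0.662 with an estimated correlation), 7 up and 2 down of 19, or 8 up and 2 down adjusted over the list alone, with Smad7 at 0.93, a call lost without enriched diet mutant replicate 1 or 2 or enriched diet wild type replicate 4, at 0.0508 to 0.0591. Cardiomyocyte genes (adjusted p = 0.607) and yolk sac genes (adjusted p = 0.322) did not pass as lists.

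Intraflagellar transport genes went both ways on the enriched diet, 8 up and 6 down of 28 on either adjustment (camera Benjamini-Hochberg adjusted p = 0.477 for the list), with Ift20 at -0.65, Wdr19 at 0.54 and Ift172 at 0.52. Of the transition zone and BBSome 7 rose and 4 fell, or 8 and 4 adjusted over the list alone (adjusted p = 0.216), with Arl13b, a small GTPase of the ciliary membrane, at 0.49 and Tmem216 at -0.64. Folate and one-carbon genes numbered 7 up and 10 down of 36, or 9 and 11 adjusted over the list alone (adjusted p = 0.814). The mitochondrial dehydrogenase Aldh1l2 rose by 3.05 ± 0.37, Mthfd2 by 1.03 and Mthfd1l by 0.68. The DNA methylation machinery went both ways (adjusted p = 0.888), 3 up and 3 down of 17 on either adjustment, with the demethylase Tet1 at 1.09 ± 0.18 and the methyltransferase Dnmt3b at -0.56. Imprinted genes numbered 6 up and 5 down of 36 on either adjustment (adjusted p = 0.527), with Ascl2 at 3.35 ± 0.61. Of p53 targets 8 rose and 4 fell of 25, or 9 and 5 adjusted over the list alone (adjusted p = 0.0787), with Sesn2 at 1.96. Simulated changes in this comparison were recovered in 6% of genes at 1.25-fold, 52% at 1.5-fold, 78% at 2-fold and 96% at 4-fold.

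**Figure D2:**
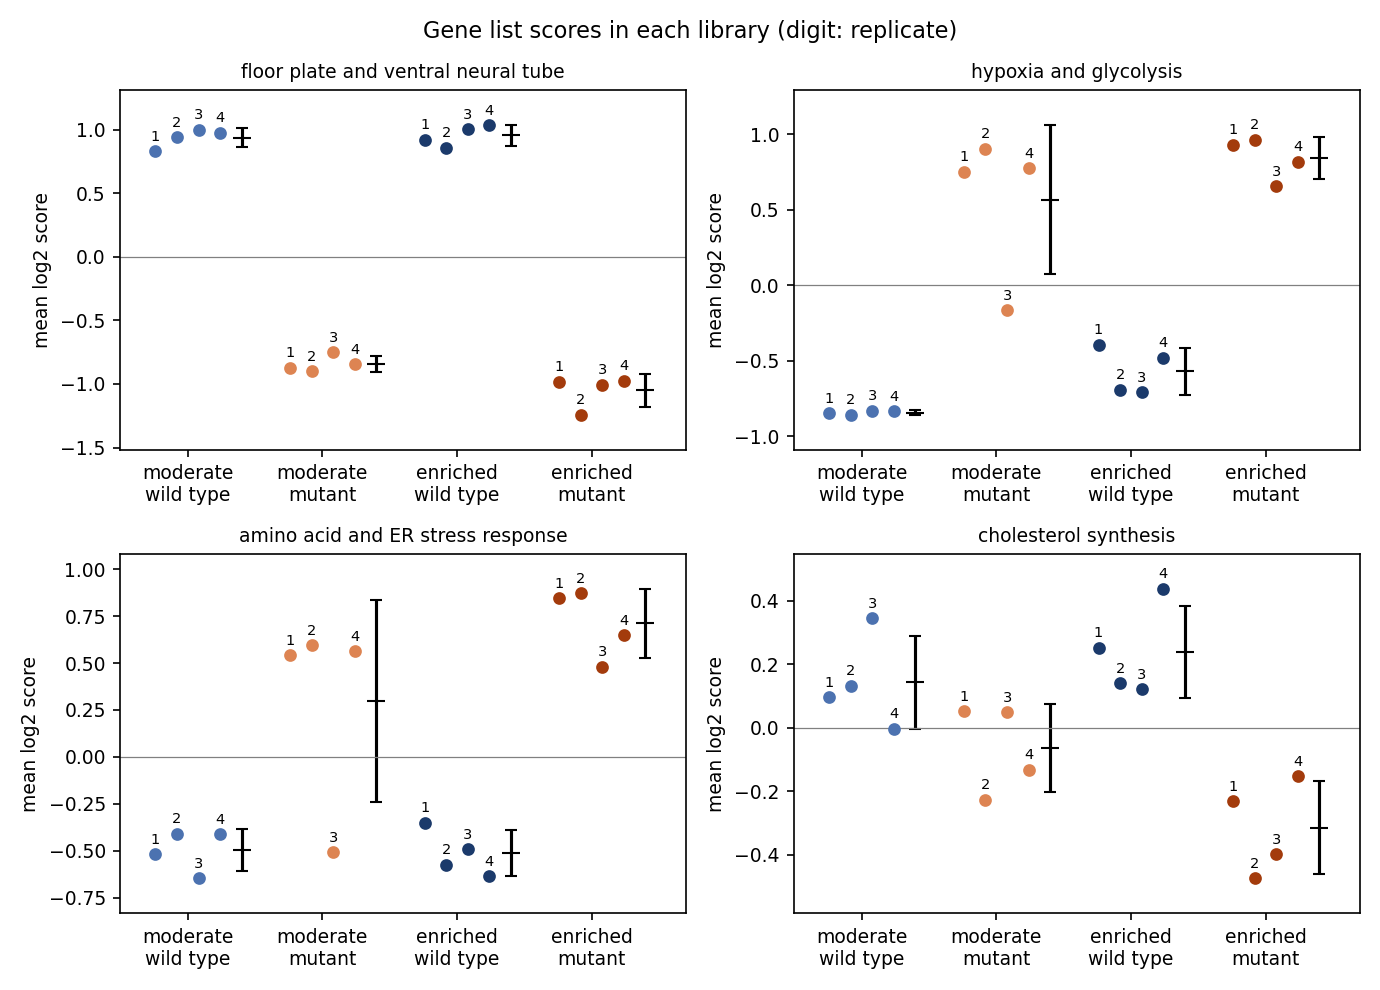
Scores of gene lists in the 16 libraries, in log2 units relative to the mean of all libraries; points are libraries coloured by group and bars show the mean and SD of 4. Floor plate scores lie at 0.831 to 1.03 in wild type and -1.24 to -0.752 in mutants, and the hypoxia score of moderate diet mutant replicate 3 is -0.164.

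The genotype effects agreed in sign on both diets for most genes past the threshold. Among the 5202 genes past it on average, the median ratio of the enriched to the moderate diet effect was 1.54, with a slope of 1.11. These genes were chosen on the average of the same 2 effects. The moderate diet effect also includes mutant replicate 3, which shared the rise of stress genes only in part or not at all. The ratio therefore does not establish a larger effect on the enriched diet. Of the genes past the threshold, 616 rose on both diets where 100.1 would by chance, 322 fell on both where 68.9 would, and 0 went opposite ways. Of the 1106 genes of the moderate diet, 1097 (99.2%) had the same sign on the enriched diet. Across all tested genes, which are not independent replicates, the fitted log2 fold changes correlated with Pearson's r = 0.73 and Spearman's rho = 0.63. Averaged over the diets, 5202 genes passed, 2519 up and 2683 down, and 456 changed by more than 2-fold. Ift88 averaged -2.10 ± 0.24 (edgeR Benjamini-Hochberg adjusted p = 1.55e-05), Shh -4.66 ± 0.14, Adm 5.37 ± 0.36 and the imprinted placental factor Ascl2 3.27 ± 0.43. Without the 3 libraries with a contradicted sex label the count was 2964. Simulated changes were recovered in 34% of genes at 1.25-fold and 88% at 2-fold.

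**Figure D3:**
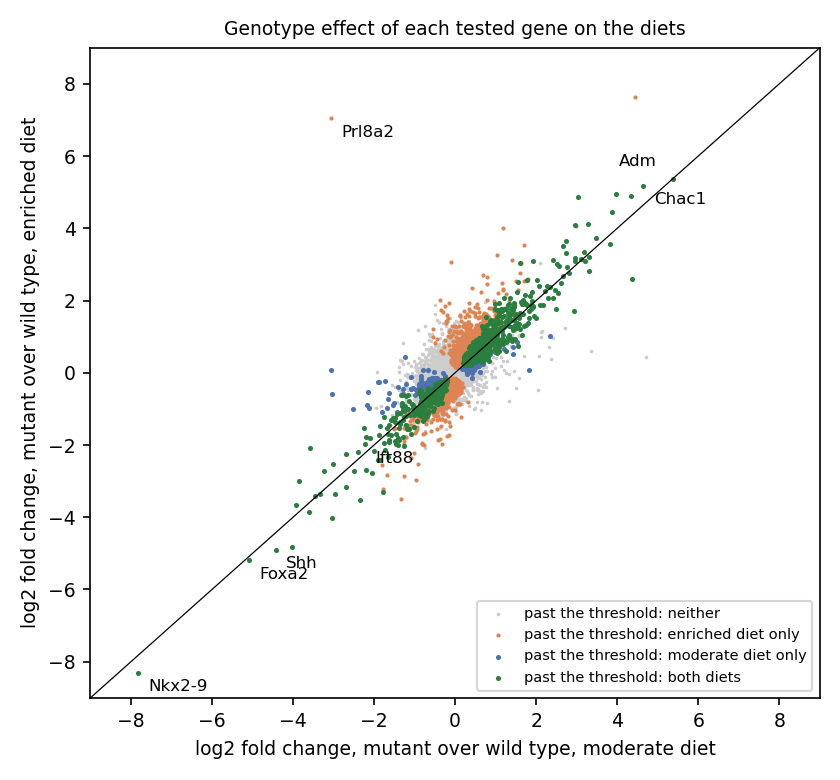
Fitted log2 fold change of mutant over wild type on the moderate diet (horizontal) and the enriched diet (vertical) for each of 14514 tested genes. The effects correlate with r = 0.73, and Nkx2-9, Foxa2 and Shh lie lowest on both diets.

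A test of the difference between the 2 genotype effects asks whether the diet altered what the loss of Ift88 does. Among the genes nearest to a difference were Runx1, a blood and endothelial factor (1.66 ± 0.36 on the log2 scale), the autophagy receptor Optn (1.29 ± 0.29), the carrier Slc25a29 (-0.84 ± 0.21) and the adhesion molecule Icam2 (-0.56 ± 0.14), each at an edgeR Benjamini-Hochberg adjusted p of 0.501. The test found 0 genes, with 1401 at an unadjusted p under 0.05 where 725.7 would be by chance, and DESeq2 and limma-voom found 0 each. The 1401 became 696 without enriched diet wild type replicate 3 and 2944 without moderate diet mutant replicate 4, the extremes without single libraries. It was 306, below the number by chance, without the 3 libraries with a contradicted sex label, and 1950 with the replicate number as a block. Ift88 differed by 0.26 ± 0.47 (adjusted p = 0.830). Cholesterol synthesis genes were lower in all 24 of 24 (camera Benjamini-Hochberg adjusted p = 5.15e-08; adjusted p = 0.956 with an estimated correlation), but 0 passed over all genes and 1 adjusted over the list alone. S phase genes were lower in 23 of 24 (adjusted p = 2.80e-06) and endothelial genes in 17 of 19 (adjusted p = 1.31e-05), each at adjusted p = 0.956 with an estimated correlation, with 0 and 6 genes adjusted over the list alone. Folate and one-carbon genes (adjusted p = 0.347) and intraflagellar transport genes (adjusted p = 0.943) did not pass. Simulated differences were recovered in 28% of genes at 1.5-fold, 64% at 2-fold and 90% at 4-fold.

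In wild type embryos the enriched diet left every gene below the threshold of the test. The genes with the smallest p were Syt7, a calcium sensor of vesicle release (-0.70 ± 0.14, edgeR Benjamini-Hochberg adjusted p = 0.967), the glycolytic enzymes Pfkl (0.32 ± 0.08) and Tpi1 (0.44 ± 0.12), Ttc9c (-0.52 ± 0.14) and the transporter Slc47a1 (5.09 ± 1.39, raised in 3 of 4 enriched diet libraries), all at the same adjusted p. Ift88 differed by -0.018 ± 0.34 (adjusted p = 0.998). The count was 0 genes with edgeR, with 354 at an unadjusted p under 0.05, 0 with limma-voom and 1 with DESeq2, which called Syt7 (-0.70 ± 0.15, Benjamini-Hochberg adjusted p = 0.0418). Without single libraries the 354 ran from 141 (enriched diet wild type replicate 1 left out) to 1295 (replicate 2 of that group left out), where 725.7 would be by chance. Some lists passed with camera, but each of these calls was lost with an estimated correlation (adjusted p = 0.921). Hypoxia and glycolysis genes were higher as a list (camera Benjamini-Hochberg adjusted p = 6.58e-05), with 0 of 24 past over all genes and 3 adjusted over the list alone. Their scores did not overlap, at -0.707 to -0.394 in enriched and -0.859 to -0.830 in moderate diet wild type. No permutation test of these scores was run in wild type. Endothelial genes were higher (adjusted p = 0.00357), with 0 on either adjustment and Egfl7 at 0.37. Yolk sac genes and head mesoderm genes (adjusted p = 0.0118 for each) were higher as well, again with 0 on either adjustment. The yolk sac and head mesoderm calls were lost too without enriched diet wild type replicate 2 (0.651 and 0.157), the former without moderate diet wild type replicate 4 (0.106) and the latter without replicate 1 (0.0827). Folate and one-carbon genes (adjusted p = 0.505), intraflagellar transport (adjusted p = 0.541), transition zone (adjusted p = 0.790), Hedgehog pathway (adjusted p = 0.182), DNA methylation (adjusted p = 0.505) and imprinted genes (adjusted p = 0.512) did not pass. Simulated diet effects in wild type were recovered in 58% of genes at 1.5-fold and 72% at 2-fold, so smaller effects would often be missed.

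In mutants no single gene passed with edgeR between the diets. The mean score of cholesterol synthesis genes was -0.0648 ± 0.139 on the moderate and -0.315 ± 0.148 (SD, n = 4) on the enriched diet in log2 units, with p = 0.0571 by a two-sided exact permutation test over 70 assignments, and their list call was lost with an estimated correlation (adjusted p = 0.628). Runx1 (log2 1.24 ± 0.26, edgeR Benjamini-Hochberg adjusted p = 0.442), Optn (0.94 ± 0.20), the mesoderm factor Tbx6 (1.74 ± 0.38) and Prl8a2 (9.87 ± 1.87), all at the same adjusted p, were among the genes with the smallest p. Ift88 differed by 0.24 ± 0.37 (adjusted p = 0.817). The count was 0 genes with edgeR, with 1565 at an unadjusted p under 0.05, and 0 with limma-voom. Without single libraries the 1565 ran from 685 (moderate diet mutant replicate 1 left out) to 3036 (replicate 4 of that group left out), where 725.7 would be by chance. It was 503 without the 3 libraries with a contradicted sex label and 2100 without the sex covariate. DESeq2 called 3, among them Prl8a2 (Benjamini-Hochberg adjusted p = 0.00121) and the RNA-binding Pcbp2 (-0.25 ± 0.06, adjusted p = 0.0490), of which Pcbp2 was chosen after its values were seen. Without enriched diet mutant replicate 1, edgeR called 1 gene, Prl8a2.

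The list calls between the diets in mutants, 9 with camera, were all lost with an estimated correlation, the smallest at adjusted p = 0.628. Cholesterol synthesis genes were lower in 24 of 24 (camera Benjamini-Hochberg adjusted p = 1.91e-11), 0 past over all genes and 15 adjusted over the list alone, with Dhcr7 at -0.30, Nsdhl at -0.45 and Hsd17b7 at -0.28. S phase genes were lower in 22 of 24 (adjusted p = 1.01e-06), with Mcm5 at -0.28 and Pcna at -0.26. Amino acid and endoplasmic reticulum stress genes were higher (adjusted p = 2.94e-05), with Atf5 at 0.51 and Ddit3 at 0.71, but the difference of the mean scores of 0.414 was 0.145 without moderate diet mutant replicate 3. Endothelial genes were lower (adjusted p = 0.000763). Early neuron genes (adjusted p = 0.000928), hypoxia and glycolysis genes (adjusted p = 0.00407), dorsal neural tube genes and p53 targets (adjusted p = 0.00883 for each) and immediate early genes (adjusted p = 0.0147) were higher. In the lists after cholesterol synthesis no gene passed on either adjustment. Leaving out moderate diet mutant replicate 3 also ended the calls of hypoxia (0.808), immediate early (0.268), dorsal neural tube and p53 genes (0.0514 each). Leaving out enriched diet mutant replicate 1 ended those of dorsal neural tube (0.633), immediate early (0.407), hypoxia (0.155) and early neuron genes (0.0516). Folate and one-carbon genes (adjusted p = 0.452), intraflagellar transport (adjusted p = 0.860), transition zone (adjusted p = 0.165), DNA methylation (adjusted p = 0.869) and imprinted genes (adjusted p = 0.860) did not pass. Simulated effects in this comparison were recovered in 56% of genes at 1.5-fold and 86% at 2-fold.

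**Figure D4:**
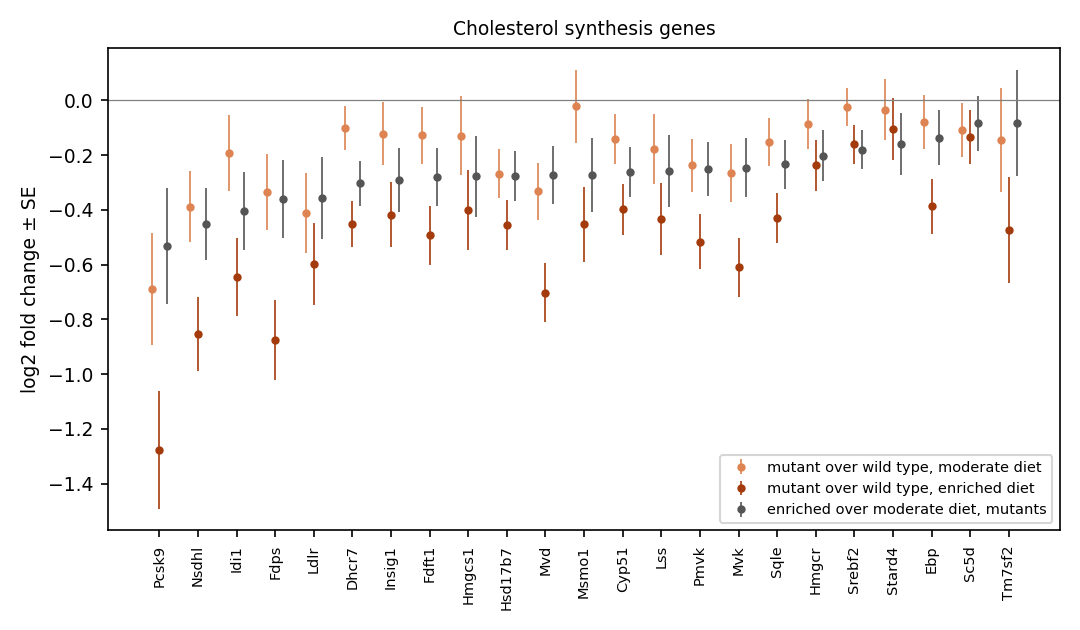
Fitted log2 fold change of cholesterol synthesis genes, for mutant over wild type on each diet and for the enriched over the moderate diet in mutants; bars show the standard error. Nsdhl lies at -0.85 in mutants over wild type on the enriched diet and at -0.45 in the diet effect in mutants.

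Averaged over the genotypes, the diet changed 0 genes with edgeR, with 526 at an unadjusted p under 0.05, 0 with limma-voom and 1 with DESeq2, again Syt7 (Benjamini-Hochberg adjusted p = 0.00931). Without single libraries the 526 ran from 310 to 846, where 725.7 would be by chance. It was 437 without the 3 libraries with a contradicted sex label, 819 with the sex read from counts and 1350 without the sex covariate. Syt7 (-0.54 ± 0.10), Inca1 (1.01 ± 0.24), Ttc9c (-0.41 ± 0.10), Slc47a1 (4.42 ± 1.09) and the recombination factor Rad51b (0.35 ± 0.09) had the smallest p, each at an edgeR Benjamini-Hochberg adjusted p of 0.997, and Ift88 differed by 0.11 ± 0.26. Hypoxia genes (camera Benjamini-Hochberg adjusted p = 5.88e-08) were higher and cholesterol synthesis genes (adjusted p = 7.63e-08) lower as lists, with 0 genes past over all genes and 0 and 1 adjusted over the list alone, and each list call was lost at adjusted p = 0.597 with an estimated correlation. Folate and one-carbon genes (adjusted p = 0.763) and intraflagellar transport (adjusted p = 0.428) did not pass. Simulated effects were recovered in 68% of genes at 1.5-fold and 86% at 2-fold.

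Whether the enriched diet moved wild type embryos the way the loss of Ift88 did was asked by correlating the diet effect in wild type with the genotype effect on the moderate diet across genes. Pearson's r was 0.289 with a covariance of 0.0265. Both effects share the moderate diet wild type libraries, and simulated groups without any effect against shared controls gave r from 0.455 to 0.515 and a mean covariance of 0.0266 over 20 simulations. When the 4 control libraries were split so that each effect had its own pair, r ran from -0.0997 to 0.150 with a mean of 0.0389 over 6 splits, and 2 of them lay below 0. The simulated spread was estimated over all 16 libraries and may not match that of the moderate diet wild type libraries. The simulated groups also held no genotype effect, so their r is not on the same scale as 0.289. The split controls do not rely on the simulation, and their r lay on both sides of 0. Shared controls could therefore account for the correlation.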

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

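The tests of the pattern in moderate diet mutant replicate 3, of the low Ift88 in moderate diet wild type replicate 2 and of single libraries behind the cholesterol difference were chosen only after the results were seen, while the permutation test of the cholesterol score was fixed before its value was seen. Chance sets a library of a group of 4 far from the others in about 1 in 20 groups, and 39 of 556 groups had such a library where 27.8 would by chance. Of these, 13 fell on moderate diet mutant replicate 3.

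Moderate diet mutant replicate 3 lay far from the other moderate diet mutants in stress genes. Its hypoxia score was -0.164 against 0.658 to 0.965 in the other 7 mutants and -0.859 to -0.394 in wild type, and its amino acid and endoplasmic reticulum stress score was -0.507, inside the wild type range. The low genes were Adm (4.84 CPM), Trib3 (2.52), Vldlr (21.0), Asns (100.5), Atf3 (8.65), Mthfd2 (108), P4ha1 (167), Tmem231 (24.3) and Psrc1 (52.9), while Dkk2 (3.15) and the erythroid factor Tal1 (23.003) were high. Its floor plate score of -0.752 lay below all wild type libraries (0.831 to 1.03), which argues against a wild type library under a mutant label. Its forebrain score differed by -0.205 from the mean of the other moderate diet mutants, far less than the stress scores did, which argues against dilution of head tissue by heart or trunk tissue as the whole cause. Some such tissue stays open: its forebrain score of -0.194 lay below the -0.113 to 0.153 of the other moderate diet mutants, and its cardiomyocyte score of 0.534 and erythroid score of 0.512 exceeded those of the other mutants (-0.400 to 0.142 and -1.55 to 0.163). Its hindbrain and Hox score of 0.853 was the highest of the 16 libraries, with the other moderate diet mutants at -0.581 to -0.144. Its trunk and posterior score of 0.133 lay above theirs (-0.590 to -0.162) but below the 0.180 of enriched diet mutant replicate 2. Hand1 (14.1 CPM, at most 0.902 elsewhere), Postn (118, 15.9), Tbx20 (5.39, 2.59), Upk3b (3.95, 0.407) and Col1a1 (226, 69.2), chosen after their values were seen, were high as well. The condition or handling of the embryo at collection may differ, as its hypoxia score of -0.164 would have it, but the labels record neither, so this stays open beside differences between mutant embryos.

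Moderate diet wild type replicate 2 held 9.30 CPM of Ift88, far below the other wild type libraries of its group. Its floor plate score of 0.942 lay inside the wild type range and above every mutant, which argues against a mutant library under a wild type label. The 10 genes that fell most in moderate diet mutants stood at a median log2 ratio of 0.0422 to the other wild type libraries (-0.27 to 0.26). They were chosen from the same data with this library counted as wild type, which favours a ratio near 0. The floor plate list was written beforehand, and its score in this library showed no fall either. Together these values argue against a large share of mutant tissue in the piece, while a small share stays open. Its Ift88 level was 46.5% of the other wild type mean. Mutants kept 10.0 to 43.1% of that mean, so a mutant copy would add to what 1 intact copy leaves. The level is lower than a simple sum of 1 intact and 1 mutant copy would give. A heterozygous embryo counted as wild type stays open, but this value does not single it out. The labels do not say how the wild type group was genotyped.

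Genotype effects on 7 lists passed a camera test of the difference between the diets, but with an estimated correlation all 7 had an adjusted p of 0.956, and the smallest by fry was 0.211. The camera Benjamini-Hochberg adjusted p was 5.15e-08 for cholesterol synthesis, 2.80e-06 for S phase and replication, 1.31e-05 for endothelial genes, 0.00137 for early neurons, 0.00390 for dorsal neural tube and roof plate, 0.00746 for amino acid and endoplasmic reticulum stress and 0.0131 for yolk sac and visceral endoderm. Leaving out single libraries ended the calls of early neurons (up to 0.0906, without enriched diet wild type replicate 2 or moderate diet wild type replicate 4), dorsal neural tube (up to 0.141, without enriched diet mutant replicate 1 or enriched diet wild type replicate 2), stress genes (up to 0.145, without any of 6 libraries) and yolk sac genes (up to 0.241, without any of 5). For cholesterol synthesis, the mean score was -0.315 ± 0.148 (SD, n = 4) in enriched and -0.0648 ± 0.139 in moderate diet mutants, a difference that gave p = 0.0571 by a two-sided exact permutation test over 70 assignments, whose smallest possible p is 0.0286. Of the 5 lists tested this way, endothelial genes gave an exact permutation p = 0.0286, with all 4 enriched diet mutants below all 4 moderate diet mutants, S phase genes p = 0.143, stress genes p = 0.171 and hypoxia genes p = 0.371. The Benjamini-Hochberg adjusted p from permutation was 0.143 for cholesterol synthesis and for endothelial genes, 0.214 for S phase and for stress genes and 0.371 for hypoxia genes. All 5 lists had passed camera for diet in mutants on these same libraries, and this adjustment covers only those 5 of the 35 lists. The permutation p-values are therefore not independent checks of the camera calls. Without any 1 of the 8 mutant libraries the score difference of -0.250 ran from -0.304 to -0.196 (± 0.10 SE, without enriched diet mutant replicate 2). The difference stayed at -0.196 or below whichever library was left out, which argues against a single library that carries it. It lay within 2 SE of 0 without some libraries, so the bound of 2 SE chosen for this test was not met. Differences between embryos without regard to diet could account for the score, since p = 0.0571 by the exact permutation test does not exclude them, and an effect of the diet itself stays open.

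Single values far from the other 3 of their group were found elsewhere. The library total of moderate diet wild type replicate 4 was 39744994 counts. In moderate diet wild type, Ttc9c stood at 136 CPM in replicate 1, Prl8a2 at 2.37 in replicate 2, and Kdm3a at 118 and Eng at 52.2 in replicate 4. In enriched diet wild type, Atf3 stood at 8.24 CPM in replicate 1, Tmem231 at 21.5 in replicate 2, Smad6 at 17.3 and Stra6 at 49.4 in replicate 3, and Aldh1a1 at 2.23, Tal1 at 16.05, Ccne1 at 122 and Gli1 at 39.6 in replicate 4. In moderate diet mutants, Nkx2-2 stood at 0.615 CPM in replicate 2, and Prl8a2 at 0.24, Nkx2-1 at 3.32 and Uhrf2 at 191 in replicate 4. In enriched diet mutants, the floor plate score was -1.24 in replicate 2, Prl8a2 stood at 189 CPM, Chac1 at 29.3 and Jund at 99.9 in replicate 3, and Slc47a1 at 7.39, Evc at 31.1, Tal1 at 7.18 and Gli1 at 23.04 in replicate 4. No explanation of these was tested here.

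Xist and Y-linked counts contradicted the sex label of 3 libraries. Moderate diet mutant replicate 1 was labelled male and had the counts of a female, and moderate diet mutant replicate 2 and moderate diet wild type replicate 2 were labelled female and had those of males. By counts, females held 330 to 645 CPM of Xist and males 0.479 to 1.98. Whether the labels of sex alone or of whole libraries were exchanged was not tested, and all 3 keep the Ift88 and floor plate levels of their genotype apart from the low Ift88 above.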

How the results depend on the processing

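Leaving out the 3 libraries with a contradicted sex label, leaving out 3 libraries with unusual values, and the sex read from counts in the list tests were chosen after seeing the data, and the other alternatives before. The genotype count on the enriched diet stayed within 1.5 times of 4524 under every alternative (3023 to 4572 without single libraries), as did that of the average over the diets (4177 to 5563) except without the 3 libraries with a contradicted sex label (2964). On the moderate diet the count of 1106 went to 105 without those 3, 719 with the libraries of the compared groups alone, 1906 at an adjusted p of 0.1 and 538 to 2107 without single libraries. It was 2107 without moderate diet mutant replicate 3 and 1628 without the 3 libraries with unusual values. With the sex read from counts and every library kept it was 1080. The fit without the 3 libraries with a contradicted sex label kept only replicates 3 and 4 of the moderate diet mutants. The cause of these changes was not tested. The diet counts of 0 became 1 in wild type, 3 in mutants and 1 on average with DESeq2, and 0 to 1 in mutants without single libraries. Ift88 kept its fall on both diets, from -2.65 to -2.01 and from -2.31 to -1.74 without single libraries. Its diet effect in wild type changed sign to 0.14 without the sex covariate, 0.0197 with the sex read from counts and 0.0863 with the compared groups alone, and ran from -0.29 to 0.0894 without single libraries. Without single libraries it ran from -0.0355 to 0.64 in mutants and from -0.0865 to 0.71 in the difference between the genotype effects, both lowest without enriched diet mutant replicate 2, and from -0.0542 to 0.29 on average, where it was below 0 without enriched diet wild type replicate 2 or moderate diet mutant replicate 1. None of these diet effects passed the threshold, and the cause was not tested.

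Of 3180 pairs of a named gene past the threshold and an alternative, 3043 kept direction and call, 137 lost the call and 0 reversed. Most named genes were picked from these same libraries for large changes or small p. That choice favours keeping the call, so the pairs say little about the other genes past the threshold. Most losses fell on genotype on the moderate diet. There 32 named genes lost the call and 30 kept it without the 3 libraries with a contradicted sex label. Leaving out a single library other than moderate diet mutant replicate 3 ended the calls of 6 to 14. Of 1222 pairs of genes not past the threshold, 1191 stayed, 20 passed and 11 reversed, all Ift88. The list tests depended most on the correlation between genes. With an estimated correlation 1 of 11 lists passed for genotype on the moderate diet, 1 of 9 on the enriched diet and 1 of 10 on average, each time the floor plate list, and 0 for diet in wild type (4 before), diet in mutants (9), the difference between the genotype effects (7) and average diet (8). With fry, which asks another question, 6 lists passed for genotype on the moderate diet, 12 on the enriched diet, 19 for the average genotype effect and 0 for the same 4 diet tests. Without single libraries 2 to 8 lists passed for diet in wild type, 6 to 14 for diet in mutants, 3 to 8 for the difference and 6 to 13 for average diet. Without the 3 libraries with a contradicted sex label 2 passed for diet in wild type. The correlation of the diet effect in wild type with the genotype effect was 0.00263, 0.0958, -0.0169, 0.101 and -0.0997 in 5 of the splits of the controls, in which shared libraries no longer add to it.

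With the replicate number as a block, 2 lists passed for diet in wild type. Whether the numbers pair the libraries stays open: 6 of 16 pairs with the same number correlated above 0.1, from -0.29 to 0.51. The highest r with the same number exceeded that with other numbers for enriched diet mutants and wild type (0.505 against 0.252). It did so too for moderate diet mutants and wild type (0.273 against 0.195) and between the mutants of both diets (0.317 against 0.218). Between the wild type groups it did not (0.0706 against 0.392). Depth limits genes near the filter of 10 counts, and the simulated recovery at 1.25-fold, 6 to 34%, limits small changes.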

Other observations

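The tests of blood content and of Ift88 by sex were chosen only after the values were seen, as were the genes of single libraries and the splits at an unadjusted p, while the decidual markers and the other splits of the libraries were fixed before their results.

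Splits of the libraries into groups of the same sizes put the counts beside chance. Of the 35 splits of the 8 libraries, 1 gave as many as the 1106 genes of the genotype on the moderate diet, the real one, and the highest other gave 163. On the enriched diet it was 1 of 35, with 4524 genes against 1, and for the average over the diets 1 of 100, with 5202 against 2624. These shares, 1 of 35 and 1 of 100, are the smallest that the splits can give. Chance is thus unlikely rather than excluded for these counts, provided that the embryos are independent. For the diet in each genotype, the difference between the genotype effects and the average diet effect the real count was 0, which every split reaches (35 of 35, 35 of 35, 100 of 100 and 100 of 100), so these counts decide nothing. The highest other counts were 0, 1175, 800 and 1261. The split with 1175, in mutants, set moderate diet mutant replicate 4 with enriched diet mutants 1, 2 and 4, exchanging 1 library of each diet, and only 2 of the other splits of the mutants gave any genes. It points to a structure among the mutants, which was not tested. Without moderate diet mutant replicate 4, the diet in mutants gave 3036 genes at an unadjusted p under 0.05. None of them passed the threshold (smallest edgeR Benjamini-Hochberg adjusted p = 0.0624). At an unadjusted p under 0.05, 15 of 35 splits gave as many as the 354 genes of the diet in wild type, with 1473 as the highest other, and 9 of 35 as many as the 1565 in mutants, with 4044. It was 19 of 100 for the 1401 genes of the difference between the genotype effects, with 4029, and 35 of 100 for the 526 of the average diet effect, with 4444. Chance is not excluded for these.

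Fewer blood cells in mutant tissue might raise other genes by share and so lift the hypoxia list. The 3 mutants whose erythroid score lay inside the wild type range of -0.404 to 1.39 had hypoxia scores of -0.164 to 0.965, all above the highest wild type score of -0.394. This argues against blood content as the whole cause of the rise.

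Prl8a2 in enriched diet mutant replicate 3 (189 CPM) may come from maternal decidua in the dissected piece. Of 23 decidual markers with counts, 2 were highest in that library, Angpt2 and Fkbp5, where 1.44 would be by chance (exact binomial p = 0.426), so the markers do not decide. The prolactin family holds near-identical copies, and reads may be shared among them. Also high in that library, by choice after the values were seen, were Htra1 at 46.5 CPM (at most 3.57 elsewhere) and the protein C receptor Procr at 12.6 CPM (at most 1.33).

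Ift88 varied among mutants with the sex read from Xist and Y-linked counts. The 3 males held 5.25 to 8.61 CPM and the 5 females 2.01 to 3.44 CPM, with p = 0.0179 by a two-sided exact permutation test over 56 assignments, the smallest it can give. Residual Ift88 RNA that differs between the sexes is a candidate explanation, found and tested on the same 8 embryos and left open. In wild type the lowest library was a male by counts as well, but the other males there held 17.9 to 20.9 CPM.

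Several libraries held genes, chosen after their values were seen, far above all others. Enriched diet mutant replicate 4 had Afp at 57.7 CPM (at most 9.26 elsewhere), Meg3 at 202 (62.3) and Firre at 104 (20.3). Moderate diet wild type replicate 2 had Ltf at 8.86 CPM (0.0286), Lcn2 at 4.31 (0.122), and the embryonic globins Hbb-bh1 at 1915 (1138) and Hba-x at 2194 (1400).

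Of the ventral genes, Nkx2-9, Shh and Foxa2 were nearly absent from all 8 mutants, although the floor plate and ventral neural tube list fell by a median of 1.37 on the log2 scale on average over the diets, with 14 of 19 genes down, 2 up and 3 not past the threshold. Nkx2-9 had 0 to 3 counts per mutant library, with 2 libraries at 0, and at most 0.123 CPM against 14.7 to 21.3 CPM in wild type. Shh had 14 to 76 counts in mutants, at most 2.18 CPM against 30.5 to 36.5 CPM, and Foxa2 6 to 26 counts, at most 0.589 CPM against 13.7 to 18.7 CPM.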
